A study of Arabidopsis thaliana with 24 samples.

How the data were processed

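Per the labels, seedlings were grown for 7 days under 16 h light and 8 h dark at 21 °C on medium with 1% sucrose, and each biological replicate pooled 30 to 50 seedlings. Libraries were made by MARS-seq, a method that sequences the 3' end of transcripts, and run on a NextSeq 500. The sources used here name bcl2fastq, cutadapt, STAR 2.4.2a, HTSeq and DESeq2 for the processing by the authors. They do not say whether molecular identifiers were collapsed, or which genome build was used, so no coordinates are given.

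The deposited table holds whole-number counts per gene and library for 16183 genes, each with at least 6 counts in its highest library. The authors also deposited a normalized signal, which equals the counts divided by 1 size factor per library (largest relative spread 9.7e-15), and 24 columns of transformed values that were not used here. For each of 11 group comparisons the authors deposited a log2 fold change, an unadjusted and an adjusted p-value, and a yes or no call. Their log2 values are coded with the opposite sign to those here, and their calls have an adjusted p under 0.05 and a log2 change of at least 1. They called 1149, 1192 and 1357 genes in roots at 1, 2 and 3 h and 996, 1064 and 585 in shoots, of which 937, 1100, 1264, 924, 915 and 512 were called here. For the root steps they called 554 and 0, for the shoot steps 498 and 523, and between organs in water 4921.

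Library totals ran from 862731 counts (root water replicate 2) to 3622300 counts (shoot water replicate 3). Counting intervals (95%) and floors (3 counts over a group) cover counting error only. A fold against a group at 0 is given as a bound at that floor, and a ratio with its interval where the lower group had 1 to 3 counts. Locus names were matched to the TAIR10.1 annotation, which gave a locus tag for 16082 genes and a symbol for 7293. The table held 78 chloroplast-encoded and 23 mitochondria-encoded genes. Shares of counts in single libraries have Wilson intervals, and CPM (counts-per-million) values are relative to the library total.

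Counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package (1.17.8), and with python 3.11.15 and matplotlib 3.10.9. The edgeR quasi-likelihood test was applied after filterByExpr (min.count 10, min.total.count 15) and TMM scaling, with Benjamini-Hochberg adjusted p under 0.05 as the threshold for a call. Each organ was fitted with its 12 libraries, and the interactions and the water comparison with all 24. Standard errors were computed as the absolute log2 fold change over the square root of the test's F. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and beside this with an estimated correlation.

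The groups, comparisons, alternatives, 24 lists (412 loci, of which 370 were in the table) and the rule for named genes were chosen before the data were examined. The rule took the 8 genes with the highest and the 8 with the lowest log2 fold change among those called, with a mean of at least 10 CPM and no overlap between the 3 libraries of each group, which chance gives in 10% of splits. It took 5 and 5 for steps, interactions and the water comparison, up to 3 members of each list past the threshold, and AOX1A, LOX1, LOX2, BAP1, ERF5 and FER1 throughout. Part of these genes is printed. List members that moved against their list (GSTU9, HB7, F6H1, MYB44, ORA59, PRX4, PRX5, PIP1;3, CRF6, RBCS1B, RBCS2B), WRKY70, the circadian genes and the list members named for interactions were named after their values were seen. Some genes are in more than 1 list: WRKY40, PRX44, PRX73, PRX64, TIP2;3, GSTF6, UGT74E2 and BCS1.

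Alternatives were median-ratio size factors, library size alone, no filter on low counts, DESeq2, a replicate block, stricter thresholds, each library left out in turn, and fits of all 24 or of only the 6 libraries compared. A further 3 were added after seeing the data: leaving out genes at least 50-fold higher in shoots, leaving out root SHAM 2 h replicate 3 with 3 h replicate 1, and leaving out organelle-encoded genes. The pipeline was tested on simulated data at these depths, with 3 libraries per group and all groups of an organ, or of both for the interaction, in the fit. In roots it found 5 of 95 genes changed 2-fold and 56 of 97 changed 4-fold, with 4 false calls. In shoots it found 7 of 96 and 67 of 95, with 4 false calls, and for the interaction 0 of 97 and 12 of 95, with 0 false calls. Few genes were changed in these data, with 65 calls in roots and 78 in shoots, so the shares found do not carry over to comparisons with more calls. The differences were also refitted for the other splits of the same libraries, 10 for 3 against 3 and 30 for the interactions. PEG alone and histidine treatments named in the series title are not analysed here.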

Results

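Seedlings of Arabidopsis thaliana Col-0 that were 7 days old were placed in water for 1 h or in salicylhydroxamic acid (SHAM) for 1, 2 or 3 h. Roots and shoots were then separated and sequenced from the 3' end as 24 libraries, 3 per group. SHAM is the hydroxamic acid of salicylate and a standard inhibitor of the mitochondrial alternative oxidase that also acts on lipoxygenases and peroxidases. The treatment label gives 1 mM SHAM, whereas the protocol text names 0.1 mM SHAM and a mixture of 30% polyethylene glycol (PEG), an osmoticum, with 1 mM SHAM. The dose, and whether the solution held PEG, are therefore open, and SHAM stands here for the treatment as labelled. Water controls were collected at 1 h, so 2 h and 3 h differences also hold time in solution. Clock time and light at harvest are not given and stay open at each exposure. The comparisons address which genes changed in each organ, when, and whether the organs differed. Fold changes are on the log2 scale with their standard error after ±, from 3 libraries per group, with adjusted p values from edgeR for genes and camera for gene lists. List counts are of tested members called higher or lower over all genes. A count adjusted over the list alone is added where it differs, and an adjusted p with an estimated correlation where the call was lost with it.

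The tissue labels matched the marker genes. In water, shoots held more transcript of genes for light harvesting and carbon fixation, and roots more of genes for root hairs, the endodermis and secreted peroxidases. The photosynthesis list had 24 of 24 higher (adjusted p = 4.9e-10, adjusted p = 0.461 with an estimated correlation) in shoots, and the class III peroxidases 16 of 18 lower (adjusted p = 4.7e-13). Root hair genes had 9 of 9 lower (adjusted p = 2.0e-08) and endodermis, stele and cortex genes 10 of 11 lower (adjusted p = 6.5e-07). GER3 (AT5G20630), a germin-like protein, and Lhca6 (AT1G19150), a photosystem I antenna protein, were at least 517-fold and 213-fold higher in shoots, with 0 counts in roots. Toward roots, the wall proteins HRGP1 (AT3G54590) and EXT10 (AT5G06640) and the root hair protein RHS13 (AT4G02270) were at least 220-fold, 155-fold and 149-fold higher, with 0 counts in shoots. Of 11704 genes tested, 2942 were higher and 2935 lower in shoots. Scaling by library size alone shifted the median gene by -1.07 and gave 1686 higher and 6402 lower, and median-ratio size factors shifted it by -0.20.

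Some libraries stood apart from their group. Root SHAM 1 h replicate 1 gave 2.73% of its counts to the photosynthesis list (95% Wilson interval 2.71 to 2.75%), against 0.11 to 0.168% in the root water libraries and the other SHAM 1 h roots. Its 115 shoot-predominant genes stood at a median 11.7% of their shoot level, against 0.426 to 1.56% in the other roots. Root SHAM 1 h replicate 2 gave 2.22% to mitochondria-encoded genes (2.21 to 2.24%), against 4.15 to 7.22% in the other root libraries. In shoots, the photosynthesis list took 18.19 to 20.25% of counts in water, 24.2 to 24.4% at 1 h, 21.1 to 21.5% at 2 h and 17.37 to 17.74% at 3 h. Organelle-encoded genes took 0.31 to 0.446% of counts in the SHAM 2 h shoots and 0.419% in SHAM 1 h replicate 3 (0.41 to 0.427%), against 1.304 to 1.647% in the other shoot libraries.

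**Figure D1:**
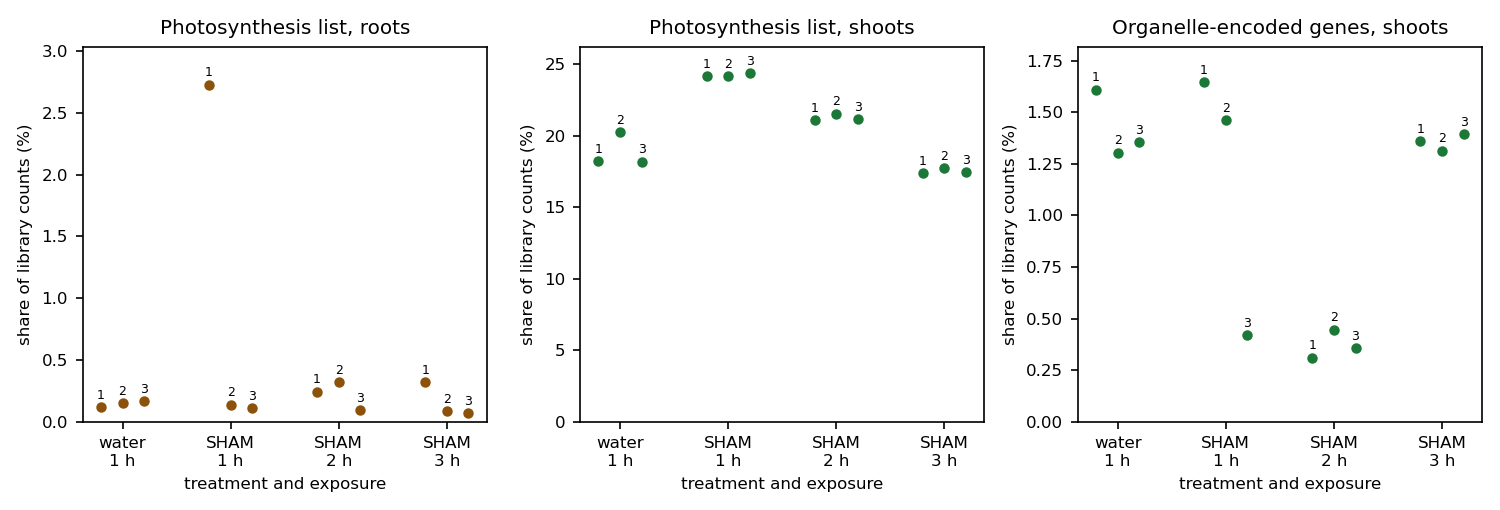
Share of library counts (%) for the photosynthesis list in roots, the same list in shoots, and organelle-encoded genes in shoots, with 1 point per library numbered by replicate and groups along the horizontal axis. Root SHAM 1 h replicate 1 stands at 2.73% in the first panel, and the SHAM 2 h shoots with SHAM 1 h replicate 3 lie at or below 0.446% in the last.

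After 1 h of SHAM, roots held more transcript of genes that respond to salicylate and of genes that detoxify foreign chemicals, and less of genes that build root hairs. GRX480 (AT1G28480), a glutaredoxin that binds TGA transcription factors, stood at 489 ± 12.5 CPM (counts-per-million, mean ± SD, n = 3) against 11.3 ± 1.12 in water. UGT75B1 (AT1G05560), a glucosyltransferase, stood at 324 ± 61.5 against 3.81 ± 0.396 CPM. NRT2.1 (AT1G08090), the main high-affinity nitrate transporter of roots, stood at 0.675 ± 0.788 against 86.1 ± 36.7 CPM. Of 10642 genes tested, edgeR called 1302, with 746 higher and 556 lower, and 1193 of these differed at least 2-fold. Scaling by library size alone shifted the median gene by -0.25 and gave 446 higher and 974 lower.

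The salicylate response list had 11 of 14 higher (11 higher and 1 lower adjusted over the list alone, adjusted p = 8.5e-17). Among them were GRX480 (5.68 ± 0.26, adjusted p = 2.1e-08) and the transcription factors WRKY62 (AT5G01900, 6.06 ± 0.42, adjusted p = 5.3e-07) and WRKY38 (AT5G22570, 5.17 ± 0.34, adjusted p = 3.8e-07), which act downstream of NPR1. The xenobiotic and electrophile detoxification list had 15 of 25 higher and 3 lower (17 higher and 5 lower adjusted over the list alone, adjusted p = 8.5e-17, adjusted p = 0.0607 with an estimated correlation). It was led by UGT75B1 (6.61 ± 0.38, adjusted p = 2.1e-07), the cytochrome P450 CYP81D11 (AT3G28740, 5.24 ± 0.34) and OPR1 (AT1G76680, 3.70 ± 0.26), a reductase of electrophilic oxylipins. Its lower members were the glutathione transferases GSTF7 (AT1G02920, -4.15 ± 0.88), GSTF6 (AT1G02930, -4.01 ± 0.75) and GSTU9 (AT5G62480, -2.81 ± 0.75). The values of GSTF6 and GSTF7 are uncertain as single genes, because these close paralogs share sequence at the 3' end.

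Iron deficiency genes had 5 of 13 higher and 1 lower (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.0018, adjusted p = 0.254 with an estimated correlation). BHLH39 (AT3G56980, 5.86 ± 0.56) helps to switch on iron uptake, OPT3 (AT4G16370, 4.78 ± 0.44) carries iron in the phloem, and IMA2 (AT1G47395, 4.67 ± 1.06) is an iron signalling peptide. The lower member was F6H1 (AT3G13610, -2.62 ± 0.56), an enzyme of coumarin synthesis. Abscisic acid and osmotic stress genes had 9 of 15 higher and 1 lower (12 higher and 1 lower adjusted over the list alone, adjusted p = 1.5e-06, adjusted p = 0.0607 with an estimated correlation). The dehydrin LTI30 (AT3G50970, 2.34 ± 0.29), the phosphatase HAI1 (AT5G59220, 3.31 ± 0.56) and CYP707A1 (AT4G19230, 2.30 ± 0.43), which breaks down abscisic acid, were higher, and the homeobox gene HB7 (AT2G46680, -1.64 ± 0.44) was lower.

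The singlet oxygen list had 5 of 10 higher (6 higher adjusted over the list alone, adjusted p = 2.7e-05, adjusted p = 0.12 with an estimated correlation), with WRKY40 (AT1G80840, 4.09 ± 0.39), ERF13 (AT2G44840, 3.89 ± 0.54) and SIB1 (AT3G56710, 3.82 ± 0.68). The touch and wound list had 7 of 14 higher and 1 lower (8 higher and 1 lower adjusted over the list alone, adjusted p = 3.3e-04, adjusted p = 0.0787 with an estimated correlation). The zinc finger gene ZAT10 (AT1G27730, 1.81 ± 0.26) and the calmodulin-like TCH3 (AT2G41100, 1.88 ± 0.31) were higher and MYB44 (AT5G67300, -1.01 ± 0.26) was lower. The mitochondrial dysfunction list had 3 of 9 higher (adjusted p = 0.00242, adjusted p = 0.216 with an estimated correlation). It holds AOX1A (AT3G22370, 2.04 ± 0.37), the alternative oxidase that SHAM inhibits, and NDB2 (AT4G05020, 1.59 ± 0.30), an external NADH dehydrogenase. The jasmonate response list had 4 of 13 higher and 1 lower (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.00772, adjusted p = 0.0718 with an estimated correlation). CYP94C1 (AT2G27690, 3.44 ± 0.40) and CYP94B3 (AT3G48520, 1.38 ± 0.30), which oxidise the active hormone, were higher, and the defence regulator ORA59 (AT1G06160, -1.26 ± 0.36) was lower. The jasmonate and oxylipin synthesis list had 1 of 11 higher (2 higher adjusted over the list alone, adjusted p = 0.016, adjusted p = 0.246 with an estimated correlation), the called member being the allene oxide cyclase AOC2 (AT3G25770, 3.22 ± 0.50).

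Root hair genes fell. The list had 8 of 9 lower (9 lower adjusted over the list alone, adjusted p = 7.7e-13), with the expansin EXPA18 (AT1G62980, -3.08 ± 0.32) and the wall protein PRP3 (AT3G62680, -2.41 ± 0.30). The class III peroxidases had 10 of 18 lower (adjusted p = 1.5e-06, adjusted p = 0.194 with an estimated correlation), with PRX73 (AT5G67400, -3.70 ± 0.51), PRX7 (AT1G30870, -2.94 ± 0.39) and PRX44 (AT4G26010, -2.81 ± 0.38). Outside these lists, NRT2.1 (-6.47 ± 0.85), the germin-like genes GLP9 (AT4G14630, -5.43 ± 0.93) and AT5G38940 (-5.39 ± 0.74), the peroxidases AT5G64110 (-4.21 ± 0.52) and AT3G49960 (-3.98 ± 0.56), and XTH26 (AT4G28850, -4.13 ± 0.45), which remodels xyloglucan, fell. WRKY51 (AT5G64810, 5.48 ± 0.79), the acyltransferase gene AT5G07860 (5.42 ± 0.37) and the kinase gene AT5G14470 (5.34 ± 0.59) rose.

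The photosynthesis list had 6 of 24 higher (19 higher adjusted over the list alone, adjusted p = 0.00199, adjusted p = 0.55 with an estimated correlation) in these roots, with RCA (AT2G39730, 3.19 ± 0.87), LHCB6 (AT1G15820, 3.01 ± 0.87) and LHCA1 (AT3G54890, 3.66 ± 1.11). This call goes with SHAM 1 h replicate 1, the library with 2.73% photosynthesis counts: without it the list had an adjusted p of 0.87. Without genes at least 50-fold higher in shoots the list had an adjusted p of 0.326 and jasmonate and oxylipin synthesis 0.0773, while the count was 1330. Without water replicates 1, 2 or 3 the count was 707, 510 or 745, and a fit of these 2 groups alone called 822. The calls of LHCA1, LHCB6 and RCA ended without any 1 of the 3 water libraries or SHAM replicate 1 (adjusted p 0.05 to 0.401), those of BAP1 and IMA2 without water replicate 1 (0.0504 and 0.0503).

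After 2 h of SHAM, genes of iron deficiency, sugar starvation and low oxygen were higher in roots beside those of salicylate and detoxification, and aquaporin transcripts were lower. BHLH39 stood at 164 ± 54.6 CPM against 0.706 ± 0.807 in water, and DIN6 (AT3G47340), an asparagine synthetase induced by darkness, at 409 ± 94.9 against 38.9 ± 8.51. The tonoplast aquaporin TIP2;2 (AT4G17340) stood at 386 ± 23.2 against 2943 ± 376 CPM. Of 10642 genes, edgeR called 915 higher and 575 lower, 1490 in all, of which 1317 differed at least 2-fold. Scaling by library size alone shifted the median gene by -0.33 and gave 575 higher and 1301 lower.

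Detoxification genes had 20 of 25 higher (adjusted p = 2.0e-34), with UGT75B1 (7.12 ± 0.39), OPR1 (4.23 ± 0.27) and the glutathione transferase GSTU24 (AT1G17170, 4.91 ± 0.35). Salicylate response genes had 10 of 14 higher (11 higher adjusted over the list alone, adjusted p = 3.7e-20), with GRX480 at 592 ± 64.0 CPM. Iron deficiency genes had 9 of 13 higher (adjusted p = 4.9e-09), with BHLH39 (7.82 ± 0.56), OPT3 (5.26 ± 0.45) and IMA2 (5.43 ± 1.05). Iron sufficiency genes went the other way, with 2 of 5 lower (adjusted p = 0.00246). The called members were the ferritin FER1 (AT5G01600, -2.34 ± 0.33) and the vacuolar iron transporter gene VTL1 (AT1G21140, -2.77 ± 0.50). Sugar starvation and darkness genes had 7 of 11 higher (9 higher adjusted over the list alone, adjusted p = 1.7e-06). Among them were DIN6 (3.72 ± 0.34), the senescence gene DIN1 (AT4G35770, 4.36 ± 0.74) and the glutamate dehydrogenase GDH2 (AT5G07440, 1.70 ± 0.34). Hypoxia core genes had 7 of 17 higher (10 higher adjusted over the list alone, adjusted p = 3.8e-05), with the transcription factors HRE2 (AT2G47520, 4.05 ± 0.44) and LBD41 (AT3G02550, 2.05 ± 0.35) and the stress gene HUP26 (AT3G10020, 2.17 ± 0.25).

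The abscisic acid list had 8 of 15 higher and 1 lower (13 higher and 1 lower adjusted over the list alone, adjusted p = 2.9e-07). LTI30 (2.92 ± 0.30), KIN2 (AT5G15970, 1.68 ± 0.22) and COR47 (AT1G20440, 1.11 ± 0.19) were higher and HB7 (-1.56 ± 0.44) was lower. The singlet oxygen list had 7 of 10 higher (8 higher adjusted over the list alone, adjusted p = 6.1e-10), with BAP1 (AT3G61190, 1.82 ± 0.25), a membrane-binding inhibitor of cell death. The touch and wound list had 7 of 14 higher (8 higher and 1 lower adjusted over the list alone, adjusted p = 2.8e-06), with TCH3 (2.74 ± 0.32) and ERF104 (AT5G61600, 1.68 ± 0.26). The mitochondrial dysfunction list had 4 of 9 higher (6 higher adjusted over the list alone, adjusted p = 4.4e-05, adjusted p = 0.0718 with an estimated correlation), with AOX1A (1.69 ± 0.37). The glucosyltransferase gene UGT74E2 (AT1G05680) of that list was 107 times its water level (95% counting interval 18.9 to 4269), with 1 count in the water libraries.

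Aquaporins had 1 of 18 higher and 11 lower (adjusted p = 6.1e-07). TIP2;2 (-2.60 ± 0.21), PIP2;1 (AT3G53420, -1.39 ± 0.19) and TIP2;3 (AT5G47450, -2.32 ± 0.33) were lower and PIP1;3 (AT1G01620, 0.70 ± 0.19) was higher. Root hair genes had 8 of 9 lower (adjusted p = 6.8e-14), with PRP3 (-3.09 ± 0.31) and PRP1 (AT1G54970, -4.18 ± 0.63). The peroxidases had 2 of 18 higher and 6 lower (2 higher and 8 lower adjusted over the list alone, adjusted p = 2.6e-04, adjusted p = 0.225 with an estimated correlation). PRX7 (-3.195 ± 0.40) and PRX57 (AT5G17820, -1.19 ± 0.17) were lower, and PRX5 (AT1G14550, 3.98 ± 1.00) and PRX4 (AT1G14540, 1.81 ± 0.56) higher. The endodermis, stele and cortex list had 3 of 10 lower (4 lower adjusted over the list alone, adjusted p = 0.00192, adjusted p = 0.0555 with an estimated correlation), with NRT2.1 (-4.42 ± 0.74) and ESB1 (AT2G28670, -0.90 ± 0.28), which shapes the Casparian strip. Cell cycle genes had 0 of 8 called (adjusted p = 0.0466, adjusted p = 0.358 with an estimated correlation). Outside the lists, XTH12 (AT5G57530) (-4.88 ± 0.39) and ADF8 (AT4G00680, -4.74 ± 0.70), which severs actin, fell.

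Several genes rose from a water level at or near 0. PCR1 (AT1G14880), a metal transport protein, was at least 179-fold higher, and the chaperone gene BIP3 (AT1G09080) of the endoplasmic reticulum and PP2-B14 (AT1G56250) at least 39.4-fold and 35.7-fold. The ATPase gene AT3G28510 was 527 times its water level (94.1 to 20837) and the acireductone dioxygenase ARD3 (AT2G26400) 256 times (45.6 to 10145). These ratios pool 3 libraries, and PCR1 and AT3G28510 stood at 242 and 217 CPM in SHAM replicate 3 but at most at 19.7 and 37.9 CPM in the others. Without water replicate 1 or 3 the count was 822 or 930. ESB1 lost its call without any 1 of 5 libraries, SHAM replicate 3 being the exception (adjusted p 0.0659 to 0.221), and cell cycle did so without SHAM replicate 3 (0.0547) and with library size alone (0.0607).

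After 3 h of SHAM, the same gene groups as at 2 h stood apart from water in roots. UGT75B1 stood at 559.9 ± 153 CPM and OPT3 at 621 ± 210 against 15.3 ± 4.05 in water, while the iron store FER1 stood at 76.2 ± 33.9 against 611 ± 98.4 CPM. LOX1, a lipoxygenase of the kind that SHAM inhibits, stood at 295 ± 183 against 107 ± 40.2 CPM. Of 10642 genes, edgeR called 1063 higher and 681 lower, 1744 in all, of which 1549 differed at least 2-fold. Scaling by library size alone shifted the median gene by -0.36 and gave 653 higher and 1563 lower.

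Detoxification genes had 20 of 25 higher (adjusted p = 1.7e-37), with UGT75B1 (7.51 ± 0.39) and GSTU24 (5.15 ± 0.35). Salicylate response genes had 11 of 14 higher (adjusted p = 2.2e-20). GRX480 stood at 6.12 ± 0.27 on the log2 scale, and NIMIN1 (AT1G02450), which binds NPR1, was at least 28.3-fold higher, with 0 counts in water. Iron deficiency genes had 9 of 13 higher (adjusted p = 1.1e-09), with BHLH39 (7.80 ± 0.56) and OPT3 (5.66 ± 0.46). Iron sufficiency genes had 3 of 5 lower (4 lower adjusted over the list alone, adjusted p = 6.3e-04), with FER1 (-2.65 ± 0.34), VTL1 (-3.48 ± 0.52) and VTL2 (AT1G76800, -1.48 ± 0.38).

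The singlet oxygen list had 7 of 10 higher (9 higher adjusted over the list alone, adjusted p = 1.5e-10), with BAP1 (2.07 ± 0.25) and ZAT12 (AT5G59820, 2.85 ± 0.37). The touch and wound list had 7 of 14 higher (9 higher adjusted over the list alone, adjusted p = 3.9e-06), with TCH3 (3.07 ± 0.32). The mitochondrial dysfunction list had 5 of 9 higher (6 higher adjusted over the list alone, adjusted p = 3.4e-06), with AOX1A (2.02 ± 0.37) and NDB2 (1.88 ± 0.30). The abscisic acid list had 8 of 15 higher (9 higher and 1 lower adjusted over the list alone, adjusted p = 3.5e-05), with LTI30 (2.72 ± 0.30). KIN1 (AT5G15960) (2.03 ± 0.36) and KIN2 (1.67 ± 0.22), also higher, are close paralogs with uncertain separate values. Sugar starvation genes had 5 of 11 higher (6 higher adjusted over the list alone, adjusted p = 7.9e-05, adjusted p = 0.079 with an estimated correlation), with DIN6 (3.82 ± 0.34) and DRM2 (AT2G33830, 1.57 ± 0.33). Hypoxia genes had 6 of 17 higher (8 higher adjusted over the list alone, adjusted p = 2.3e-04), with HRE2 at 23.9 ± 7.26 against 1.62 ± 0.483 CPM.

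Aquaporins had 10 of 18 lower (13 lower adjusted over the list alone, adjusted p = 6.8e-10), with TIP2;2 (-2.74 ± 0.21), TIP2;3 (-2.98 ± 0.34) and PIP2;1 (-1.72 ± 0.19). Root hair genes had 7 of 9 lower (8 lower adjusted over the list alone, adjusted p = 9.0e-12), with PRX73 (-4.28 ± 0.55) and PRP1 (-4.07 ± 0.60). The peroxidases had 2 of 18 higher and 5 lower (2 higher and 6 lower adjusted over the list alone, adjusted p = 0.0128, adjusted p = 0.408 with an estimated correlation), with PRX5 (4.44 ± 1.00) and PRX4 (2.095 ± 0.56) again higher. The endodermis list had 3 of 10 lower (4 lower adjusted over the list alone, adjusted p = 0.00377, adjusted p = 0.0727 with an estimated correlation), including the beta-glucosidase PYK10 (AT3G09260, -1.26 ± 0.40). Cell cycle genes had 1 of 8 lower (adjusted p = 0.047, adjusted p = 0.349 with an estimated correlation), the called member being the DNA clamp PCNA1 (AT1G07370, -2.26 ± 0.58). Outside the lists, XTH12 (-5.21 ± 0.40) and the flavonoid hydroxylase TT7 (AT5G07990, -3.90 ± 0.55) fell.

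PCR1 was at least 355-fold, PP2-B14 at least 54.6-fold and BIP3 at least 40.1-fold higher than in water at 3 h. AT3G28510 stood at 940.0 times (168 to 37157) and ARD3 at 276 times (49.2 to 10922) its water level. In SHAM replicate 1 PCR1 and AT3G28510 stood at only 19.0 and 29.3 CPM. Without water replicate 1 the count was 1001, without SHAM replicate 2 or 3 1151 or 1161, and without SHAM 2 h replicate 3 and 3 h replicate 1 together, chosen after seeing the data, 1875, while with all 24 libraries in the fit the call of PYK10 ended (adjusted p 0.11). Calls that ended without 1 library were LOX1 and PYK10 (any but SHAM replicate 1, adjusted p 0.063 to 0.171), VTL2 and PCNA1 (water replicate 2 or SHAM replicates 2 or 3, and VTL2 also water replicate 1, 0.0624 to 0.0868) and the peroxidases (SHAM replicate 1, 0.121), and cell cycle with library size alone (0.0595).

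**Figure D2:**
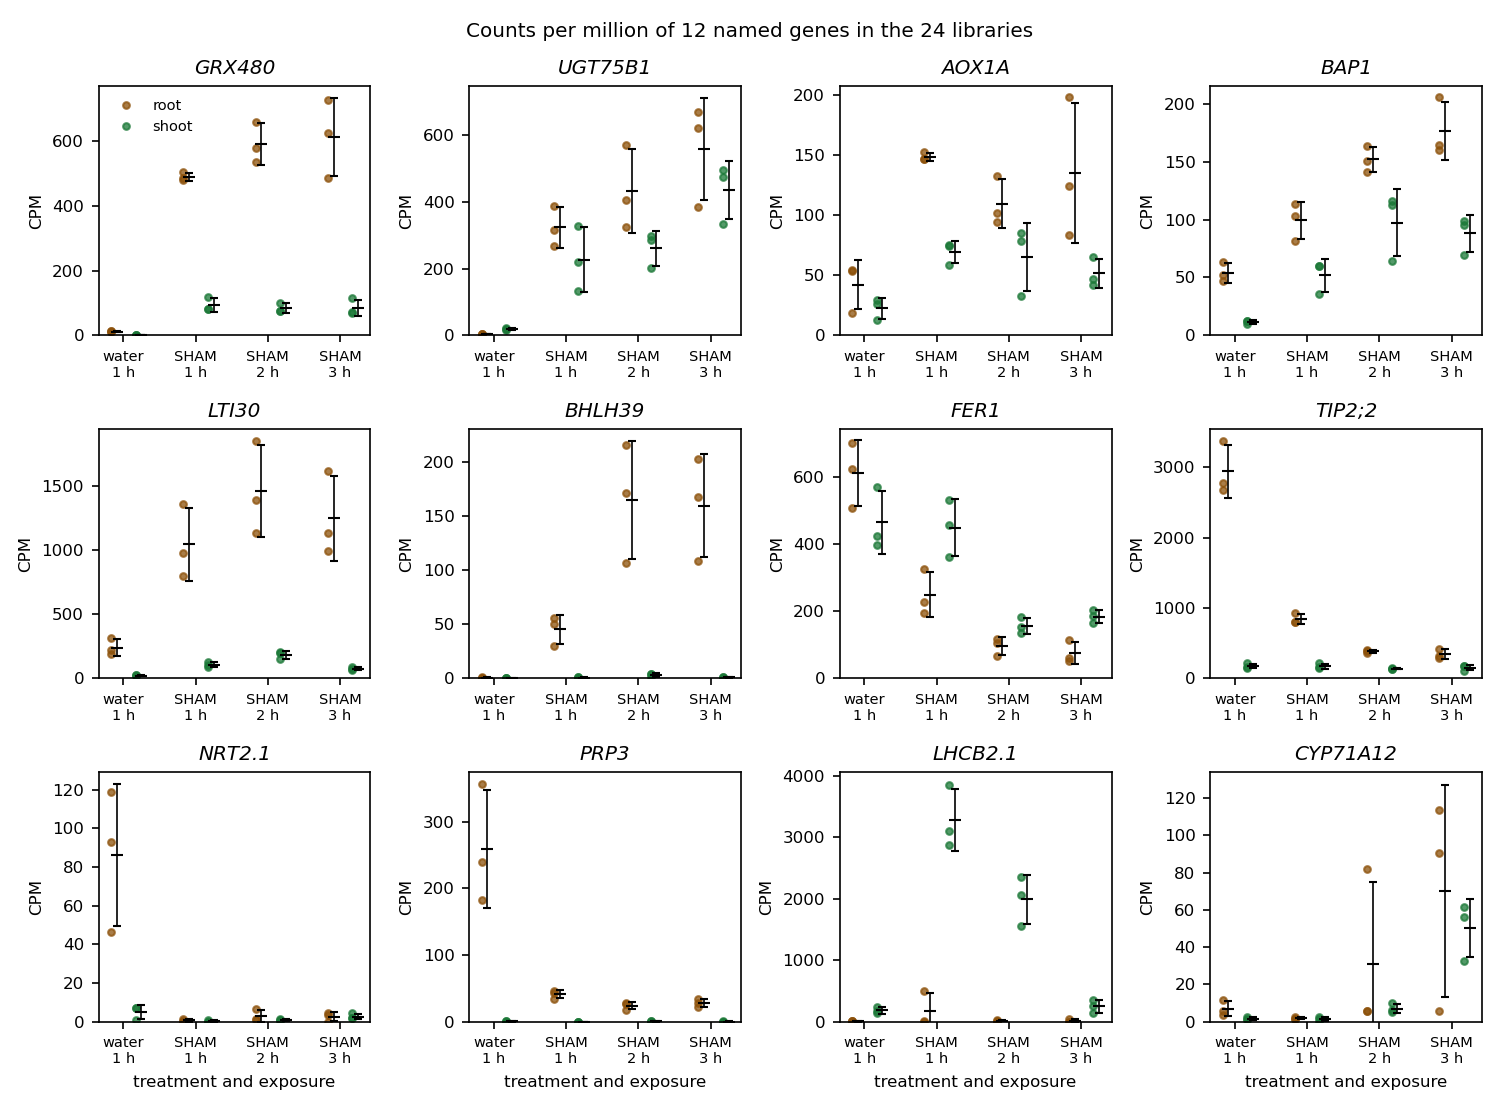
Linear CPM for 12 named genes, with 1 point per library, the mean as a bar and the SD as an error line (n = 3), roots in brown and shoots in green, groups along the horizontal axis. GRX480 and UGT75B1 stand above water in both organs at each exposure, while LHCB2.1 stands at 3278 CPM in shoots at 1 h and 249 CPM at 3 h.

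After 1 h of SHAM, shoots shared the salicylate and detoxification response with roots, and photosynthesis genes were higher. GRX480 stood at 93.0 ± 21.1 CPM against 0.893 ± 0.513 in water, and DMR6 (AT5G24530), which hydroxylates salicylate, at 51.9 ± 17.1 against 1.97 ± 0.77. LHCB2.1 (AT2G05100), an antenna protein of photosystem II, stood at 3278 ± 511 against 184 ± 53.2 CPM. DIN1, a dark-induced senescence gene, stood at 321 ± 38.0 against 2916 ± 420 CPM. Of 8570 genes tested, edgeR called 802 higher and 642 lower, 1444 in all, of which 1161 differed at least 2-fold. Scaling by library size alone shifted the median gene by -0.24 and gave 542 higher and 988 lower.

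Detoxification genes had 14 of 17 higher (adjusted p = 4.0e-19), with CYP81D11 (4.88 ± 0.38, adjusted p = 2.9e-06), UGT75B1 (3.83 ± 0.31, adjusted p = 3.3e-06) and OPR1 (3.25 ± 0.28, adjusted p = 5.0e-06). Salicylate response genes had 9 of 11 higher (11 higher adjusted over the list alone, adjusted p = 8.5e-15). Among them were GRX480 (7.06 ± 0.45, adjusted p = 1.2e-06), DMR6 (5.08 ± 0.43, adjusted p = 3.8e-06), WRKY70 (AT3G56400, 5.11 ± 0.83) and NIMIN2 (AT3G25882, 4.07 ± 0.49). Abscisic acid and osmotic stress genes had 7 of 17 higher (9 higher and 1 lower adjusted over the list alone, adjusted p = 3.1e-08). The dehydrins ERD10 (AT1G20450, 3.25 ± 0.26) and LTI30 (2.53 ± 0.20) and KIN1 (2.39 ± 0.25) rose. The singlet oxygen list had 5 of 8 higher (6 higher adjusted over the list alone, adjusted p = 8.5e-06, adjusted p = 0.0968 with an estimated correlation), with BAP1 (2.45 ± 0.38) and ERF6 (AT4G17490, 1.68 ± 0.26). The touch and wound list had 5 of 13 higher (8 higher adjusted over the list alone, adjusted p = 3.7e-05, adjusted p = 0.158 with an estimated correlation), with WRKY53 (AT4G23810, 4.37 ± 0.36), WRKY40 (2.57 ± 0.36) and ZAT10 (1.32 ± 0.28).

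The photosynthesis list had 12 of 24 higher and 1 lower (13 higher and 1 lower adjusted over the list alone, adjusted p = 3.3e-10). LHCB2.1 (4.41 ± 0.31), LHCB1.1 (AT1G29920, 4.05 ± 0.30) and LHCB2.2 (AT2G05070, 4.16 ± 0.32) led it, and their separate values are uncertain because these paralogs share sequence. The lower member was the Rubisco small subunit gene RBCS2B (AT5G38420, -0.77 ± 0.25). Jasmonate and oxylipin synthesis genes had 6 of 14 higher (8 higher and 1 lower adjusted over the list alone, adjusted p = 0.00409, adjusted p = 0.207 with an estimated correlation). The higher members included AOC3 (AT3G25780, 3.25 ± 0.43), OPR3 (AT2G06050, 1.81 ± 0.29) and the lipoxygenase LOX3 (AT1G17420, 2.22 ± 0.37). Jasmonate response genes had 3 of 8 higher (adjusted p = 0.039, adjusted p = 0.135 with an estimated correlation), with CYP94C1 (2.82 ± 0.33), CYP94B3 (4.16 ± 0.76) and the storage protein VSP2 (AT5G24770, 1.40 ± 0.39). The mitochondrial dysfunction list had 3 of 5 higher and 1 lower (adjusted p = 0.0207, adjusted p = 0.207 with an estimated correlation). NDB2 (2.51 ± 0.35), AOX1A (1.85 ± 0.35) and the dicarboxylate carrier DIC2 (AT4G24570, 1.74 ± 0.37) were higher and CRF6 (AT3G61630, -0.93 ± 0.25) was lower.

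The auxin list had 1 of 2 higher (2 higher adjusted over the list alone, adjusted p = 0.00125, adjusted p = 0.0658 with an estimated correlation). The called member was IAA19 (AT3G15540, 3.996 ± 0.38), an early auxin response gene, at 32.7 ± 9.06 against 2.31 ± 0.419 CPM. Cytosolic ribosomal proteins had 3 of 20 higher (4 higher adjusted over the list alone, adjusted p = 0.0147, adjusted p = 0.19 with an estimated correlation), with RPL4D (AT5G02870, 1.12 ± 0.25), RPSAA (AT1G72370, 0.89 ± 0.19) and RPL27AC (AT1G70600, 0.89 ± 0.20). Sugar starvation and darkness genes had 3 of 11 lower (2 higher and 4 lower adjusted over the list alone, adjusted p = 0.0475, adjusted p = 0.304 with an estimated correlation), with DIN1 (-2.95 ± 0.32), DRM2 (-2.45 ± 0.31) and DRM1 (AT1G28330, -1.40 ± 0.25). The median member of that list was at 0.03 while its mean was at -0.50, the direction of the test. Outside the lists, the legume lectin gene AT5G03350 (5.38 ± 0.40), the amino acid transporter LHT7 (AT4G35180, 5.37 ± 0.57), the glutaredoxin-like AT4G15670 (5.22 ± 0.60) and the starch synthase GBSS1 (AT1G32900, 5.03 ± 0.38) rose. The chaperone gene AT5G23240 (-5.08 ± 0.48), the demethylase JMJD5 (AT3G20810, -4.51 ± 0.56), which acts with the circadian clock, and GER3 (-4.45 ± 0.40) fell.

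Without shoot water replicate 2 the count was 898 and without SHAM 1 h replicate 2 it was 918, and with all 24 libraries in the fit the calls of the sugar list, VSP2, RPL27AC, LHCB1.1 and RPSAA ended (adjusted p 0.116, 0.0924, 0.0608, 0.0806 and 0.0722). Calls that ended were VSP2 (without water replicates 1 or 2 or SHAM replicates 2 or 3, adjusted p 0.0695 to 0.0804) and the sugar list (without water replicates 1 or 2 or SHAM replicates 1 or 2, 0.0554 to 0.12), with RPL4D, RPL27AC and the ribosomal list without water replicate 2 (0.0541, 0.0606 and 0.0554), the list also without SHAM replicate 1 (0.0608).

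After 2 h of SHAM, salicylate response and detoxification genes were higher in shoots, and counts of chloroplast- and mitochondria-encoded genes were lower. PCC1 (AT3G22231), a gene of defence and the clock, stood at 137 ± 17.7 CPM against 2.06 ± 0.648 in water, and BAP1 at 97.51 ± 29.1 against 11.4 ± 1.77. FER1 stood at 157 ± 24.2 against 465 ± 92.8 CPM. Of 59 organelle-encoded genes tested, 40 were lower and 0 higher, against 3 lower and 1 higher at 1 h and 0 lower and 2 higher at 3 h. Of 8570 genes, edgeR called 718 higher and 638 lower, 1356 in all, of which 1101 differed at least 2-fold, and without organelle-encoded genes 1329. Scaling by library size alone shifted the median gene by -0.07 and gave 604 higher and 703 lower.

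Detoxification genes had 14 of 17 higher (adjusted p = 3.1e-22), with UGT75B1 (3.86 ± 0.31) and the glucosyltransferase UGT73B5 (AT2G15480, 3.28 ± 0.31). Salicylate response genes had 8 of 11 higher (adjusted p = 3.5e-14), with GRX480 (6.74 ± 0.45), DMR6 (4.99 ± 0.42) and the calmodulin-binding regulator CBP60G (AT5G26920, 3.77 ± 0.34). The singlet oxygen list had 7 of 8 higher (adjusted p = 2.6e-11), with BAP1 (3.22 ± 0.37) and SIB1 (4.02 ± 0.48). The touch and wound list had 6 of 13 higher (9 higher adjusted over the list alone, adjusted p = 6.1e-07, adjusted p = 0.131 with an estimated correlation), with WRKY53 (4.38 ± 0.36) and ERF104 (1.70 ± 0.21). The abscisic acid list had 9 of 17 higher (adjusted p = 7.5e-07), with LTI30 (3.13 ± 0.21), KIN1 (2.39 ± 0.24) and COR47 (1.27 ± 0.18).

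The photosynthesis list had 9 of 24 higher and 2 lower (9 higher and 3 lower adjusted over the list alone, adjusted p = 2.2e-04, adjusted p = 0.241 with an estimated correlation). LHCB2.1 (3.49 ± 0.30) and LHCB1.1 (3.31 ± 0.29) were higher and RBCS2B (-0.86 ± 0.25) and RBCS1B (AT5G38430, -1.72 ± 0.28) lower. The mitochondrial dysfunction list had 3 of 5 higher (4 higher adjusted over the list alone, adjusted p = 0.0436, adjusted p = 0.389 with an estimated correlation), with AOX1A (1.57 ± 0.34), NDB2 (1.58 ± 0.35) and DIC2 (1.34 ± 0.36). Sugar starvation genes had 4 of 11 higher (adjusted p = 0.0436, adjusted p = 0.389 with an estimated correlation), with DIN6 (2.09 ± 0.35), the amino acid breakdown gene BCAT2 (AT1G10070, 2.15 ± 0.38) and GDH2 (1.78 ± 0.47). Outside the lists, PCC1 (6.01 ± 0.43), WRKY54 (AT2G40750, 5.18 ± 0.39), LHT7 (5.64 ± 0.56) and AT5G14470 (4.71 ± 0.41) rose. The stress gene AT2G15960 (-6.42 ± 1.43), the protease DEG14 (AT5G27660, -4.79 ± 1.48) and the chloroplast-encoded ATCG00310 (-5.38 ± 1.43) and ATCG00720 (-5.04 ± 0.73) fell.

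Without shoot water replicate 2 the count was 861 and without SHAM 2 h replicate 1 it was 761, and with all 24 libraries in the fit the calls of the photosynthesis list, LHCB1.1, LHCB2.1, LOX1 and DIC2 ended (adjusted p 0.249, 0.14, 0.0534, 0.14 and 0.0771). Calls that ended were DEG14 (any library but water replicate 3, adjusted p 0.0589 to 0.158), DIC2 (without water replicates 1 or 2 or SHAM replicate 1, 0.0727 to 0.133), ATCG00310 (without water replicate 2 or SHAM replicates 1 or 2, 0.0744 to 0.0999) and GDH2 and LOX1 (without SHAM replicate 2, or water replicate 3 and 2 respectively, 0.0558 to 0.0722), as well as the mitochondrial list (without SHAM replicates 1 or 2, 0.133 and 0.0619) and the sugar list (without water or SHAM replicate 3, 0.0916 and 0.19).

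After 3 h of SHAM, genes for camalexin and indole glucosinolates, which are defence compounds made from tryptophan, were higher in shoots, and photosynthesis genes were no longer called. PCC1 stood at 513 ± 36.9 CPM and WRKY54 at 59.7 ± 2.90 CPM. CYP71A12 (AT2G30750), an enzyme of the camalexin route, stood at 50.1 ± 15.4 against 1.63 ± 0.885 CPM in water, and CYP83B1 (AT4G31500), of the glucosinolate route, at 897 ± 79.2 against 233 ± 70.3. LHCB2.1 stood at 249 ± 104 against 184 ± 53.2 CPM. Of 8570 genes, edgeR called 541 higher and 230 lower, 771 in all, of which 663 differed at least 2-fold.

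The camalexin and indole glucosinolate list had 6 of 8 higher (7 higher adjusted over the list alone, adjusted p = 9.1e-08). CYP71A12 (5.08 ± 0.50), CYP83B1 (1.96 ± 0.24) and the tryptophan synthase AT3G54640 (1.40 ± 0.25) rose. CYP71A12 is uncertain as a single gene, because CYP71A13 is a close paralog. Detoxification genes had 14 of 17 higher (15 higher adjusted over the list alone, adjusted p = 4.4e-32), with UGT75B1 (4.56 ± 0.32) and OPR1 (3.78 ± 0.29). Salicylate response genes had 8 of 11 higher (9 higher adjusted over the list alone, adjusted p = 7.0e-15), with GRX480 (6.71 ± 0.45) and NIMIN2 (4.40 ± 0.49). The singlet oxygen list had 7 of 8 higher (8 higher adjusted over the list alone, adjusted p = 8.4e-14), with BAP1 (2.99 ± 0.37). The touch and wound list had 7 of 13 higher (9 higher adjusted over the list alone, adjusted p = 8.0e-08, adjusted p = 0.0825 with an estimated correlation), with ZAT10 (2.64 ± 0.29) and WRKY53 (2.55 ± 0.36).

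The mitochondrial dysfunction list had 4 of 5 higher (adjusted p = 1.1e-04, adjusted p = 0.0825 with an estimated correlation), with DIC2 (2.86 ± 0.37), NDB2 (1.83 ± 0.35) and the transporter ABCB4 (AT2G47000, 2.05 ± 0.40). Jasmonate and oxylipin synthesis genes had 4 of 14 higher (5 higher adjusted over the list alone, adjusted p = 0.00247, adjusted p = 0.231 with an estimated correlation), with LOX1 (AT1G55020, 2.19 ± 0.32), AOC3 (2.32 ± 0.43) and LOX4 (AT1G72520, 2.48 ± 0.60). The abscisic acid list had 3 of 17 higher (6 higher adjusted over the list alone, adjusted p = 0.0215, adjusted p = 0.131 with an estimated correlation), with LTI30 (1.81 ± 0.20). Aquaporins had 2 of 15 lower (3 lower adjusted over the list alone, adjusted p = 0.00128, adjusted p = 0.248 with an estimated correlation), the called members being PIP2;1 (-1.12 ± 0.21) and PIP1;4 (AT4G00430, -0.91 ± 0.19). Iron sufficiency genes had 2 of 6 lower (adjusted p = 0.032, adjusted p = 0.117 with an estimated correlation), with FER1 (-1.32 ± 0.22) and the iron-sulfur protein NEET (AT5G51720, -1.42 ± 0.39).

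Outside the lists, PCC1 (7.85 ± 0.45), WRKY54 (5.60 ± 0.39) and the wall-associated kinase WAK1 (AT1G21250, 5.14 ± 0.47) rose, and the defence gene LURP1 (AT2G14560) was 125 times its water level (34.3 to 1039). The glutaredoxin AT1G06830 (-3.76 ± 0.71), the peroxidase PRX45 (AT4G30170, -2.57 ± 0.35) and the cysteine synthase OASA1 (AT4G14880, -2.54 ± 0.51) fell. Without water replicates 1 or 2 the count was 469 or 457, and without SHAM replicates 1 or 2 it was 417 or 510, and with all 24 libraries in the fit the calls of AOX1A, NEET and iron sufficiency ended (adjusted p 0.0922, 0.372 and 0.0803). Calls that ended without some 1 library, at the highest adjusted p, were AOX1A (water replicate 1, 0.178), KIN2 (water replicate 1, 0.132), LOX4 (water replicate 3, 0.0848), NEET (SHAM replicate 1, 0.172) and iron sufficiency (water replicate 1, 0.0766), and RPL16B (AT4G18730, -2.96 ± 0.82), NdhM (AT4G37925, -3.21 ± 0.75) and MOD1 (AT2G05990, -2.55 ± 0.61) (SHAM replicate 1, 0.162, 0.0973 and 0.102) and the chloroplast-encoded ATCG00530 (5.16 ± 1.28) (water replicate 2, 0.0919).

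**Figure D3:**
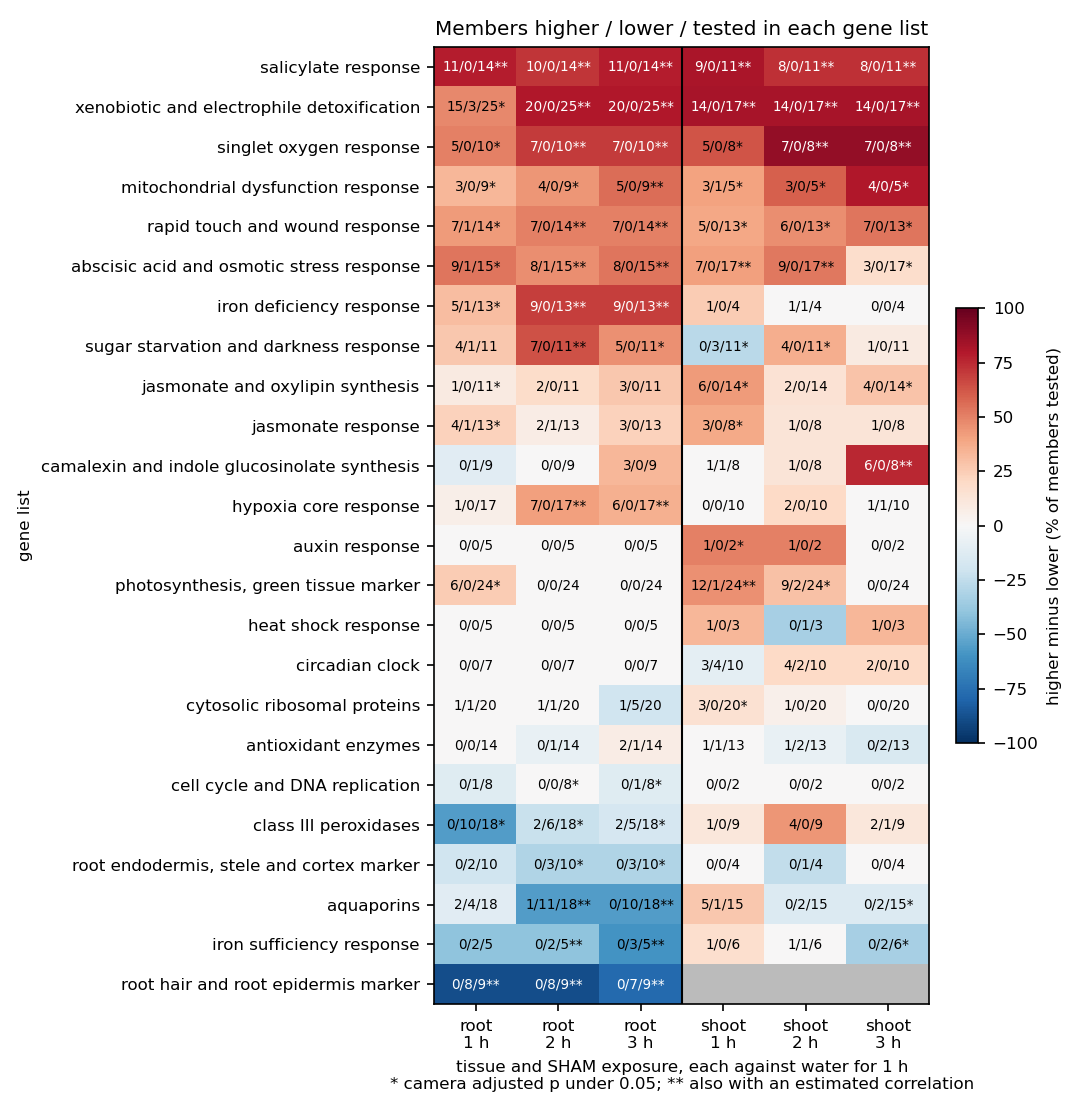
Heat map of the 24 gene lists (vertical) by the 6 comparisons of SHAM with water (horizontal), where each cell gives members higher, lower and tested and the colour the share higher minus the share lower (%). An asterisk marks camera adjusted p under 0.05 and a double asterisk the same with an estimated correlation, and the salicylate response list carries the double mark in each of the 6 comparisons.

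**Figure D4:**
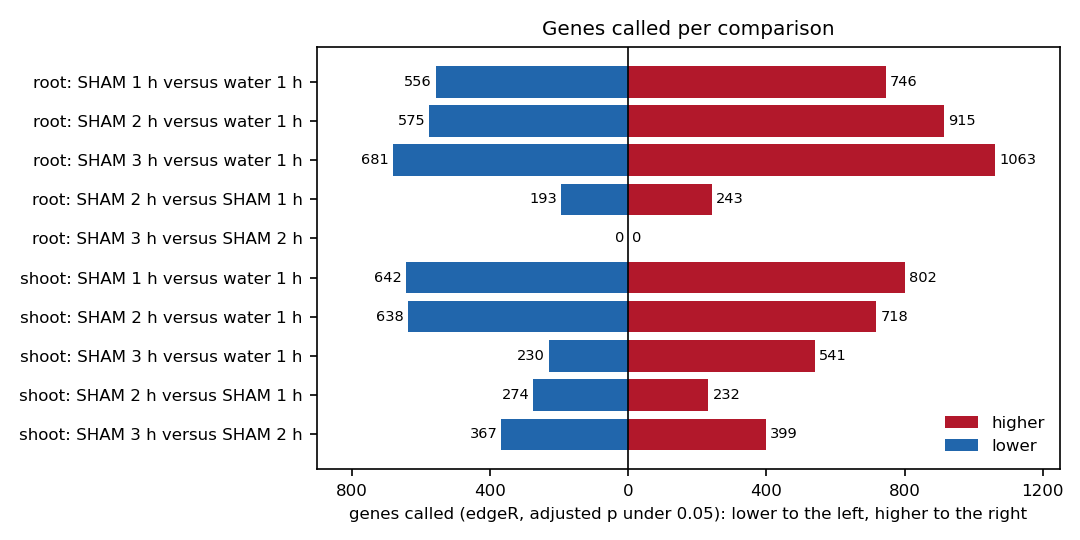
Genes called lower (left bars) and higher (right bars) by edgeR for the 6 comparisons with water and the 4 steps between exposures, from 0 on a linear axis of gene number. Counts run from 0 for roots at 3 h against 2 h to 1744 for roots at 3 h against water.

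Enzymes that SHAM inhibits, and 3 other genes fixed beforehand, were followed at every exposure. AOX1A stood at 148 ± 3.31, 109 ± 20.1995 and 135 ± 58.2 CPM in roots at 1, 2 and 3 h against 42.0 ± 20.4 in water, and was called each time. In shoots it stood at 69.2 ± 9.12, 65.4 ± 28.4 and 51.6 ± 12.1 against 22.5 ± 8.72 CPM. The call at 3 h (1.18 ± 0.34, adjusted p = 0.045 in edgeR) ended without any library but water replicate 2 (adjusted p 0.072 to 0.178). LOX1 was at 0.56 ± 0.54 and 1.00 ± 0.54 in roots at 1 h and 2 h (adjusted p = 0.48 and 0.24) and at LOX1 (1.80 ± 0.55, adjusted p = 0.0364) at 3 h. In shoots LOX1 was at 0.92 ± 0.33, 1.27 ± 0.32 and 2.19 ± 0.32, and the first of these did not pass (adjusted p = 0.07, and 0.0209 without SHAM replicate 1). LOX2 (AT3G45140) did not pass in shoots (1.19 ± 0.44, 0.94 ± 0.44 and 0.25 ± 0.44, adjusted p = 0.084, 0.17 and 0.77, the first at 0.0289 without SHAM replicate 1) and had too few counts for a test in roots. FER1 in roots at 1 h was at FER1 (-1.06 ± 0.32, adjusted p = 0.0439), a call that ended without any library but SHAM replicate 1 (adjusted p 0.0924 to 0.131), and in shoots at 1 h at 0.21 ± 0.22 (adjusted p = 0.56). BAP1 rose in both organs at each exposure, from BAP1 (1.12 ± 0.24, adjusted p = 0.00958) in roots at 1 h. ERF5 (AT5G47230) did not pass in roots (adjusted p = 0.67, 0.81 and 0.78) or shoots (0.49, 0.2 and 0.052, the last at 0.0262 without SHAM replicate 1).

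Other fixed lists did not pass the list test against water in either organ, although single members were called. Antioxidant enzymes had adjusted p values of 0.561, 0.789 and 0.826 in roots at 1, 2 and 3 h and 0.562, 0.363 and 0.411 in shoots. Heat shock genes had 0.302, 0.448 and 0.444 in roots and 0.214, 0.957 and 0.0729 in shoots, with only 5 of 16 tested in roots and 3 in shoots. Circadian clock genes had 0.302, 0.714 and 0.902 in roots and 0.203, 0.32 and 0.0768 in shoots.

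From 1 h to 2 h in roots, several lists passed, but none kept its call with an estimated correlation. The xenobiotic list had 5 of 25 higher (10 higher adjusted over the list alone, adjusted p = 1.0e-08, adjusted p = 0.213 with an estimated correlation) and the sugar list 4 of 11 higher (6 higher adjusted over the list alone, adjusted p = 2.2e-05, adjusted p = 0.196 with an estimated correlation). Iron deficiency had 3 of 13 higher (4 higher adjusted over the list alone, adjusted p = 7.8e-05, adjusted p = 0.225 with an estimated correlation) and hypoxia 3 of 17 higher (5 higher adjusted over the list alone, adjusted p = 0.00749, adjusted p = 0.213 with an estimated correlation). Aquaporins had 6 of 18 lower (7 lower adjusted over the list alone, adjusted p = 2.2e-05, adjusted p = 0.177 with an estimated correlation). Jasmonate response (lower), photosynthesis (lower) and singlet oxygen response (higher) also passed (adjusted p = 0.0133, 0.0133 and 0.0185, adjusted p = 0.177, 0.789 and 0.511 with an estimated correlation). The fall of photosynthesis genes, with 0 of 24 called, goes with SHAM 1 h replicate 1 at 2.73% of counts, while replicates 2 and 3 stood at 0.137 and 0.11% and the 2 h libraries at 0.092 to 0.323%. PCR1 (5.24 ± 1.23), AT3G18250 (5.00 ± 0.89), AT1G19530 (4.61 ± 0.58) and the aminotransferase BCAT7 (AT1G50090, 4.46 ± 0.76) rose. The wall genes AGP19 (AT1G68725, -2.91 ± 0.63), AT4G16980 (-2.81 ± 0.63) and PG2 (AT1G70370, -2.46 ± 0.34) and the phenylpropanoid ligase 4CL5 (AT3G21230, -2.72 ± 0.41) fell. In edgeR 243 genes were higher and 193 lower, 436 in all, and 203 and 267 with library size alone. The count was 173 or 259 without SHAM 1 h replicate 1 or 2 and 231, 151 or 58 without SHAM 2 h replicate 1, 2 or 3. A fit of these 2 groups alone called 0, with 653 by DESeq2 on the root libraries. PCR1, AGP19 and AT4G16980 lost their calls without SHAM 2 h replicate 3 (adjusted p 0.177, 0.103 and 0.119) and without 2 or 3 other libraries each.

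From 2 h to 3 h in roots, edgeR called 0 of 10642 genes, with 176 at an unadjusted p under 0.05, and DESeq2 and the deposited results of the authors also had 0. The libraries did not group by exposure: SHAM 2 h replicates 1 and 2 with 3 h replicate 1 correlated at 0.938 to 0.957 across genes, and 2 h replicate 3 with 3 h replicates 2 and 3 at 0.967 to 0.975. Libraries of different sets correlated at 0.905 to 0.932. PCR1 followed these sets, at 92.7 ± 130 CPM at 2 h and 190.4 ± 151 at 3 h, as did CYP71A12 at 31.1 ± 44.1 and 70.0 ± 56.7. Aquaporins (lower), photosynthesis (lower), xenobiotic detoxification (higher), ribosomal proteins (lower) and peroxidases (higher) passed (adjusted p = 5.6e-04, 5.6e-04, 9.3e-04, 0.0378 and 0.0379, adjusted p = 0.498, 0.682, 0.63, 0.63 and 0.63 with an estimated correlation).

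From 1 h to 2 h in shoots, the sugar starvation list passed as higher and the photosynthesis list as lower, neither with an estimated correlation. IAA19 fell. The sugar list had 5 of 11 higher (6 higher adjusted over the list alone, adjusted p = 2.9e-08, adjusted p = 0.0717 with an estimated correlation) and the circadian list 3 of 10 higher (5 higher adjusted over the list alone, adjusted p = 3.1e-04, adjusted p = 0.125 with an estimated correlation). Photosynthesis genes had 2 of 24 lower (4 lower adjusted over the list alone, adjusted p = 7.9e-04, adjusted p = 0.332 with an estimated correlation) and auxin genes 1 of 2 lower (2 lower adjusted over the list alone, adjusted p = 8.7e-04, adjusted p = 0.0951 with an estimated correlation). Aquaporins (lower), singlet oxygen response (higher) and jasmonate response (lower) also passed (adjusted p = 0.0171, 0.019 and 0.0304, adjusted p = 0.361, 0.332 and 0.158 with an estimated correlation). BCAT2 (2.97 ± 0.41), the threonine aldolase THA1 (AT1G08630, 2.83 ± 0.44) and AT4G25580 (3.51 ± 0.52) rose. The arabinogalactan protein AGP21 (AT1G55330, -6.51 ± 1.21), the thylakoid protein AT1G52220 (-4.31 ± 1.00) and the ribosomal AT1G77940 (-4.17 ± 0.94) fell, as did 19 of the 59 organelle-encoded genes. In edgeR 232 genes were higher and 274 lower, 506 in all, and 364 and 191 with library size alone, which shifted the median gene by 0.18. The count was 225, 87 or 1149 without SHAM 1 h replicate 1, 2 or 3, 166, 247 or 303 without SHAM 2 h replicate 1, 2 or 3, and 139 in a fit of these 2 groups alone. Without SHAM 2 h replicate 1 the calls of AGP21 and AT1G52220 ended (adjusted p 0.0512 and 0.104, the second also in 4 other fits), and that of AT1G77940 did so there and in 3 other fits without 1 library (adjusted p 0.0692 to 0.0853).

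From 2 h to 3 h in shoots, camalexin and indole glucosinolate genes rose, while part of the photosynthesis genes fell. The camalexin list had 5 of 8 higher (6 higher adjusted over the list alone, adjusted p = 8.3e-09). Photosynthesis genes had 1 of 24 higher and 9 lower (2 higher and 12 lower adjusted over the list alone, adjusted p = 8.3e-09, adjusted p = 0.0918 with an estimated correlation). Abscisic acid genes had 7 of 17 lower (1 higher and 7 lower adjusted over the list alone, adjusted p = 0.00168, adjusted p = 0.0918 with an estimated correlation). Ribosomal proteins had 2 of 20 lower (6 lower adjusted over the list alone, adjusted p = 0.00594, adjusted p = 0.276 with an estimated correlation). Sugar starvation (lower) and aquaporins (lower) also passed (adjusted p = 0.0235 and 0.0285, adjusted p = 0.393 and 0.546 with an estimated correlation). The B-box gene BBX28 (AT4G27310, -3.79 ± 0.25) stood at 5.66 ± 0.771 against 76.0 ± 5.18 CPM, and NEET (-3.60 ± 0.42), GAT1_2.1 (AT1G15040, -3.50 ± 0.38) and AT2G29670 (-5.00 ± 0.68) also fell. The chloroplast-encoded ATCG00500 (4.24 ± 0.65), ATCG00940 (4.03 ± 0.66) and ATCG00860 (3.94 ± 0.75) rose, and 25 of the 59 organelle-encoded genes were higher. In edgeR 399 genes were higher and 367 lower, 766 in all, and 374 and 405 with median-ratio size factors. The count was 391, 463 or 410.0 without SHAM 2 h replicate 1, 2 or 3 and 294 or 316 without 3 h replicate 1 or 2.

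Calls overlapped between exposures within an organ. In roots, 651 genes were called in the same direction at 1 h and 2 h, 629 at 1 h and 3 h and 1223 at 2 h and 3 h. In shoots these numbers were 733, 344 and 444. Overlaps of higher genes were 441, 410 and 805 in roots and 428, 261 and 351 in shoots, against 64.1, 74.5, 91.4, 67.2, 50.6 and 45.3 for independent calls. Overlaps of lower genes were 210, 219 and 418 and 305, 83 and 93, against 30.0, 35.6, 36.8, 47.8, 17.2 and 17.1. The comparisons share 3 water libraries, too few to divide, so part of the excess can come from them. In 20 simulated data sets without any change per organ the correlation of log2 fold changes across genes was 0.48 to 0.518 and the covariance 0.127 to 0.137. The measured correlations were 0.703, 0.64 and 0.926 in roots and 0.588, 0.393 and 0.633 in shoots, with covariances of 0.842, 0.792 and 1.16 and of 0.635, 0.366 and 0.649. Without root water replicate 1, 2 or 3 the root overlaps of 1 h with 2 h were 359, 350.0 and 407 and of 1 h with 3 h 351, 333 and 397. That of 2 h with 3 h was 681 or 775 without replicate 1 or 3. Without shoot water replicate 2 the shoot overlaps were 454, 211 and 278. That of 1 h with 3 h was 224 without water replicate 1 and 227 without SHAM 3 h replicate 1. Genes higher at all 3 exposures numbered 391 in roots and 232 in shoots, and genes lower at all 3 numbered 174 and 62.

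Roots and shoots shared part of the response. GRX480, UGT75B1, OPR1, BAP1 and LTI30 rose in both organs at each exposure. Across 7606 genes tested in both, which are not independent replicates, fold changes correlated at r = 0.27 at 1 h, 0.439 at 2 h and 0.535 at 3 h (rho = 0.173, 0.349 and 0.411), with jackknife standard errors of r over the libraries of 0.246, 0.0675 and 0.134. Genes higher in both numbered 236, 300 and 281 against 63.7, 66.2 and 60.3 for independent calls, and genes lower in both 30, 51 and 23 against 15.3, 17.35 and 6.47. Opposite calls numbered 20, 22 and 11 against 66.1, 71.9 and 39.8. The correlation at 2 h was 0.27 without a filter on low counts.

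The difference between the organs was tested as an interaction over 11704 genes. In the fit of shoots alone, only 9 peroxidases, 2 auxin, 4 iron deficiency and 10 hypoxia genes had enough counts for a test. For the other members of these lists the shoot side of the interaction rests on few counts. At 1 h the shoot response lay above the root response for peroxidases, with 3 of 18 higher (5 higher adjusted over the list alone, adjusted p = 0.00436, adjusted p = 0.438 with an estimated correlation) and PRX62 (AT5G39580, 5.31 ± 0.95). So it did for salicylate genes, with 3 of 15 higher (4 higher adjusted over the list alone, adjusted p = 0.0242, adjusted p = 0.277 with an estimated correlation) and PAD4 (AT3G52430, 4.22 ± 1.06), and for auxin genes, with 1 of 5 higher (adjusted p = 0.018, adjusted p = 0.277 with an estimated correlation) and IAA19 (3.101 ± 0.45). It lay below for circadian genes, with 2 of 10 lower (4 lower adjusted over the list alone, adjusted p = 0.0072, adjusted p = 0.277 with an estimated correlation), ELF4 (AT2G40080, -2.29 ± 0.36) and BOA (AT5G59570, -3.79 ± 0.52). Sugar starvation (lower) and ribosomal proteins (higher) also passed (adjusted p = 0.0242 and 0.0427, adjusted p = 0.454 and 0.619 with an estimated correlation).

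At 2 h another split of the libraries called 528 genes against 391 for the real one, and such splits exclude chance at no exposure. The shoot response then lay above that of roots for aquaporins, with 4 of 18 higher (5 higher adjusted over the list alone, adjusted p = 6.9e-04, adjusted p = 0.443 with an estimated correlation) and TIP2;2 (2.23 ± 0.36). It lay below for iron deficiency genes, with 1 of 13 lower (4 lower adjusted over the list alone, adjusted p = 0.0219, adjusted p = 0.443 with an estimated correlation), and for sugar starvation genes, with 1 of 12 lower (4 lower adjusted over the list alone, adjusted p = 0.0414, adjusted p = 0.443 with an estimated correlation). At 3 h it lay below for sugar starvation genes, with 2 of 12 lower (5 lower adjusted over the list alone, adjusted p = 1.1e-04, adjusted p = 0.167 with an estimated correlation) and DIN1 (-5.14 ± 0.81). The same held for hypoxia genes, with 2 of 17 lower (3 lower adjusted over the list alone, adjusted p = 0.00295, adjusted p = 0.195 with an estimated correlation) and LBD41 (-2.86 ± 0.47), and iron deficiency genes, with 2 of 13 lower (4 lower adjusted over the list alone, adjusted p = 0.00295, adjusted p = 0.275 with an estimated correlation) and OPT3 (-5.04 ± 0.65). It lay above for camalexin and indole glucosinolate genes, with 1 of 9 higher (adjusted p = 5.2e-04) and CYP83B1 (2.97 ± 0.57). Abscisic acid (lower), aquaporins (higher) and iron sufficiency response (higher) also passed (adjusted p = 0.0245, 0.00295 and 0.0326, adjusted p = 0.195, 0.322 and 0.171 with an estimated correlation).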

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

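Tests of a SHAM effect on green tissue genes in roots, of libraries prepared in sets that cross the groups, and of a SHAM effect tied to 2 h were chosen after the result was seen. Libraries named in tests were picked from values already seen.

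Photosynthesis genes were called higher in roots after 1 h of SHAM, with a list median log2 fold change of 3.01. Without root SHAM 1 h replicate 1 the median was 0.01 (0.0146), the adjusted p went from 0.00199 to 0.87, and 1 instead of 6 of 24 members was called. A SHAM effect on these genes would place all 3 treated libraries above water, and 1 of 3 was. Shoot RNA in this root library is a candidate explanation, since 115 shoot-predominant genes stood there at 11.7% of their shoot level, against 0.426 to 1.56% in the other roots. All 24 list genes are also detected in root water libraries, so the list marks an amount and not presence.

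No gene was called between roots at 3 h and at 2 h by edgeR or DESeq2. The split that trades 2 h replicate 3 for 3 h replicate 1 called 716 genes and the others 0. It runs along sets that already correlate apart and so decides nothing. An exchange of these libraries, preparation in sets that cross the groups and no further change cannot be told apart. Bounds set beforehand on the 716 calls were wrong, since such sets would give calls without an exchange or a change between 2 h and 3 h. The photosynthesis share was 0.242 to 0.323% in one set and 0.0714 to 0.092% in the other, a ratio of 2.63 between their nearest members, and no label gives a set. In shoots this exchange and each other split called 0 genes against 766 as labelled, which cannot show whether the shoots mirror the sets.

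Counts of organelle-encoded genes were lower in shoots after 2 h of SHAM, with 40 of 59 called lower. Whether such 3' end counts follow transcript amount was not tested. A SHAM effect tied to 2 h stays open, since only 1 of the 9 libraries of other exposures, SHAM 1 h replicate 3 at 0.419%, lay below the highest 2 h library at 0.446%. A mislabelled 1 h library stays open as well. Over 1404 nuclear genes SHAM 1 h replicate 3 lay 0.561 of the way from replicate 2 to the 2 h mean (0.527 to 0.606). This interval (1000 bootstrap draws of genes) covers no spread between libraries. The photosynthesis share of this library, 24.4%, was near the 24.2% of 1 h replicates 1 and 2, against 21.1 to 21.5% at 2 h. Its correlations across genes were 0.955, 0.954 and 0.900 with 2 h replicates 1, 2 and 3, and 0.836 and 0.915 with 1 h replicates 1 and 2. These rank by the partner's library total and decide nothing. Loss of short transcripts in preparation also stays open. From 1 h to 2 h 123 genes under 600 nt had a median of -0.25 and 4500 genes of 1000 to 2000 nt had -0.04, a difference of -0.21.

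The interaction of organ and SHAM called 694 genes at 1 h (231 with a higher and 463 with a lower response in shoots), 391 at 2 h (96 and 295) and 202 at 3 h (51 and 151), by edgeR over 11704 genes. With library size alone the splits were 247 and 319, 184 and 160, and 124 and 63, the median gene shifting by 0.12, 0.34 and 0.39. Median-ratio size factors gave 272 and 339 at 1 h, with shifts of 0.15 at 1 h and 0.11 at 2 h. At 1 h the count was 446, 320.0 and 451 without root water replicate 1, 2 or 3, 406 and 308 without shoot water replicate 2 or 3. It was 365, 370.0 and 1127 without shoot SHAM replicate 1, 2 or 3. At 2 h it was 195, 243 and 230.0 without root water replicate 1, 2 or 3, 253 without shoot water replicate 2, 258 and 236 without root SHAM replicate 1 or 2, and 214 without shoot SHAM replicate 2. At 3 h it was 81, 119 and 105 without root water replicate 1, 2 or 3, and 125 and 88 without shoot water replicate 1 or 2. It was 123, 117 and 130.0 without root SHAM replicate 1, 2 or 3, and 103 and 79 without shoot SHAM replicate 1 or 2. Without root SHAM 2 h replicate 3 and 3 h replicate 1, chosen after seeing the data, it was 412 at 2 h and 157 at 3 h.

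At 1 h the response in shoots exceeded that in roots for AT4G39670 (6.76 ± 1.44), BGLU22 (AT1G66280, 6.63 ± 1.64), GSTF6 (6.24 ± 1.04), PRX62 (5.31 ± 0.95) and FLOT1 (AT5G25250, 4.69 ± 0.96). It lay below that in roots for GER3 (-9.36 ± 1.65), CA2 (AT5G14740, -6.50 ± 1.54), AT4G17245 (-6.12 ± 1.73), PDX1L4 (AT2G38210, -5.91 ± 0.78) and SIG4 (AT5G13730, -5.44 ± 1.09). Without root SHAM 1 h replicate 1 the adjusted p of GER3, CA2, AT4G17245 and SIG4 was 0.9999, 0.531, 0.184 and 0.0755. That of AT4G39670 and BGLU22 without shoot water replicate 3 was 0.0546 and 0.0946. At 2 h the higher responses were in AT4G39670 (6.49 ± 1.40), GulLO5 (AT2G46740, 5.02 ± 1.23), AT1G21525 (4.27 ± 0.62), WRKY53 (3.68 ± 0.71) and PRX62 (3.67 ± 0.91). The lower were in AT2G15960 (-8.44 ± 1.77), AT1G06360 (-7.61 ± 1.65), UPI (AT5G43580, -6.54 ± 1.42), AT1G56150 (-6.43 ± 1.102) and AT3G11110 (-6.26 ± 0.73). Their calls ended without shoot water replicate 3 for AT4G39670 (0.0607), GulLO5 (0.136) and PRX62 (0.0874), and without root SHAM 2 h replicate 1 for AT1G06360 (0.0992). At 3 h the higher responses were in AT5G01740 (3.44 ± 0.54), SOT16 (AT1G74100, 3.39 ± 0.88), CYP710A1 (AT2G34500, 3.204 ± 0.83), CYP83B1 (2.97 ± 0.57) and AT1G66180 (2.80 ± 0.37). The lower were in AT1G56150 (-6.97 ± 1.07), SIG4 (-5.15 ± 1.08), DIN1 (-5.14 ± 0.81), OPT3 (-5.04 ± 0.65) and AT5G50175 (-5.00 ± 1.00). SOT16 and CYP710A1 lost their calls in 11 and 9 of 12 fits without 1 library (adjusted p up to 0.136 and 0.126), SIG4 without root water replicate 1 (0.0873) and AT5G50175 without shoot water replicate 2 (0.103). With root and shoot of the same exposure and number as a block in edgeR, the 1 h calls of AT4G17245, BGLU22 and CA2 ended (adjusted p 0.169, 0.077 and 0.242). So did those of AT1G06360 and GulLO5 at 2 h (0.0795 and 0.116) and of CYP710A1, SIG4 and SOT16 at 3 h (0.156, 0.0873 and 0.109). Where the water libraries of an organ were at 0 (shoots for AT4G39670, BGLU22 and GulLO5, roots for GER3, AT4G17245, SIG4 and AT1G06360), the fitted value depends on the prior count.

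For the interactions, 30 splits regrouped SHAM and water libraries within each organ. They stand for no SHAM effect in either organ, not for equal effects. At 1 h 1 split, the real one, called as many genes (highest other 420.0), and at 3 h 1 did (highest other 116). At 2 h 2 splits called 391 or more, the highest other 528. These splits therefore cannot exclude chance for a difference between the organs at any exposure. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real counts of 1302, 1490.0, 1744, 1444, 1356 and 771 against water, 766 for shoots from 2 h to 3 h, 436 for roots from 1 h to 2 h and 5877 between organs in water stood against a highest other of 0, and 506 for shoots from 1 h to 2 h against 197.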

How the results depend on the processing

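The leave-one-out ranges were 510 to 1533, 822 to 1136 and 1001 to 1718 for roots against water at 1, 2 and 3 h, and 898 to 1449, 761 to 1201 and 417 to 729 for shoots. For the steps they were 58 to 369 and 0 to 0 in roots and 87 to 1149 and 294 to 645 in shoots, for the interactions 308 to 1127, 195 to 341 and 79 to 150, and for the organs in water 5049 to 5904. Overlaps between exposures ranged over 350 to 635, 333 to 632 and 681 to 1082 in roots and 454 to 694, 211 to 343 and 278 to 443 in shoots, and root to shoot correlations over 0.121 to 0.392, 0.388 to 0.45 and 0.458 to 0.609. At an adjusted p under 0.01 edgeR called 419, 695 and 809 genes in roots, 752, 668 and 361 in shoots, 32 for roots from 1 h to 2 h, 109 and 223 for the shoot steps, and 156, 154 and 67 for the interactions. Fits of only the 2 groups called 822 for roots at 1 h, 0 for roots from 1 h to 2 h and 139 for shoots from 1 h to 2 h. With a replicate block the steps from 1 h to 2 h called 282 and 307 and the interactions 293, 200 and 81. Residual correlations between equal replicate numbers ran from -0.62 to 0.54 within an organ. Between root and shoot of the same exposure and number they ran from -0.39 to 0.38. They show no steady pairing of the libraries but cannot exclude one. All 24 libraries in the fit gave 507 for shoots from 2 h to 3 h. The interaction at 3 h called 125 without a filter and 376 with DESeq2. Root to shoot correlations at 2 h were 0.27 without a filter, 0.273 with DESeq2 and 0.345 in the fit of all 24, and at 3 h 0.369 without a filter and 0.372 with DESeq2. With root SHAM 2 h replicate 3 and 3 h replicate 1 left out, chosen after seeing the data, the root steps called 217 and 230, the second between sets that already correlate apart. Lists past the threshold with an estimated correlation numbered 2 for roots at 1 h and 4, 4 and 4 for shoots. Of 72 list calls against water, 36 were lost with an estimated correlation, 3 with library size alone, 4 with the replicate block, 3 in the fit of all 24 and 5 in the fit of 2 groups. The reversed value was the photosynthesis list in roots at 1 h, with an adjusted p of 0.87 without SHAM replicate 1 and 2.7e-07 without SHAM replicate 2. Of 364 values of named genes, 3 lost a call with median-ratio size factors, 8 with library size alone, 4 without a filter, 24 with the replicate block and 6 with DESeq2, and of 2364 leave-one-out values 210 lost a call, 3 gained one and 0 reversed.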

Other observations

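Circadian clock genes were called in both directions in shoots at 1 h and 2 h, and the list was not called against water. At 1 h COL1 (AT5G15850, 2.60 ± 0.40), PRR5 (AT5G24470, 1.54 ± 0.45) and GI (AT1G22770, 1.28 ± 0.34), which peak in daytime, were higher. The evening complex genes ELF4 (-2.65 ± 0.25) and ELF3 (AT2G25930, -0.90 ± 0.29) and the related BOA (-2.90 ± 0.41) were lower, as was PRR3 (AT5G60100, -2.997 ± 0.58). At 2 h PRR7 (AT5G02810, 2.56 ± 0.55), PRR5, GI and COL1 were higher and ELF4 and BOA lower, and at 3 h COL1 and GI were higher. Sugar starvation genes already differed between the organs in water, with 8 of 12 higher and 2 lower (9 higher and 2 lower adjusted over the list alone, adjusted p = 0.00107, adjusted p = 0.243 with an estimated correlation) in shoots, TPS10 (AT1G60140, -2.52 ± 0.69) and GDH2 (-1.49 ± 0.41) lying higher in roots. Roots also held more ribosomal protein transcripts, with 12 of 20 lower (adjusted p = 0.0131, adjusted p = 0.461 with an estimated correlation), and auxin response transcripts, with 4 of 5 lower (adjusted p = 0.0448, adjusted p = 0.421 with an estimated correlation).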
